A study of Danio rerio with 2 samples.

How the data were processed

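Whole zebrafish larvae (Danio rerio) were compared at 108 hours post-fertilization. Per the labels' protocols, larvae were kept at 28.5 °C, with 0.003% PTU from 24 hours to block pigment, and were genotyped singly. RNA of about 60 larvae of 1 genotype was pooled and poly(A) RNA was selected in 2 rounds. Libraries were made for SOLiD sequencing with 18 cycles of amplification after selection of fragments of 100-200 bp. There was 1 wildtype library and 1 library of homozygous clbn (caliban) mutants, so no value has a replicate error. The groups were taken from the genotype labels. Submitters' processing notes name the genome build Zv9. Aligner, counting tool and multi-mapping rule are not given in the sources used here.

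One table of 55660 introns of Refseq gene models was used. The authors deposited whole read counts per intron and library, without normalization, and every listed intron has at least 1 read in both libraries. Introns without a read in one or both libraries are therefore not analysed here, which includes any intron seen in the mutant library only. Per the file headers, the authors also gave intron levels in RPuKM, a form of RPKM, which divides reads by the unique length of the intron and the number of reads in the library. The library sizes behind these values, recovered from counts, lengths and RPuKM, were 28309779 reads for wildtype and 25718058 for the mutant. Deposited log2 RPuKM columns and the authors' fold change (ratio) columns were not used for any result. Per the file headers, a gene expression value was given for each Refseq ID and library with no unit. These values were found to be whole reads scaled by unique exonic length and library size in the same way. For 10223 of 10223 gene values (100%), whole reads and a whole length came out within 1e-06 bp. The smallest whole solution was used. In simulated data for 2000 genes it was the true read number for 82.6%, and too low by a common factor for 17.4%, which widens intervals and weakens tests. The recovered length is then too low by the same factor, so minimums on gene reads or length can drop such genes. The authors' intron retention coefficient equalled RPuKM over the gene value. The header ties it to U12-type introns, but it is filled for introns of all kinds.

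For 1893 introns no gene value was given, 1121 of them listed under several Refseq IDs. In 1121 of those 1121 introns (100%) both read counts were whole multiples of the number of IDs, so that reads had been counted once per ID. These counts were divided by the number of IDs wherever they were used. Start positions in the table fit a count from 0, since end minus start equals the stated length, and 1 was added to print positions on Zv9 counted from 1. Symbols came from a Refseq table of the GRCz12tu assembly, used for names only, which matched 9797 of 10223 gene IDs (95.8%).

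Minor (U12-type) introns are a rare class that a separate spliceosome removes. The table has no column for intron class, and no genome of the build was at hand to read splice sites. As set before the data were examined, introns of genes on a fixed list of genes (94 symbols matched) known or thought to hold a U12-type intron stood in for that class. The list was assembled from background knowledge, not every member need hold such an intron in zebrafish, and most introns of these genes are of the major class. A median over the list is therefore diluted.

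Retention was compared as the log2 ratio, mutant over wildtype, of intronic reads divided by gene reads, with a pseudocount of 0.5 on both. Introns with a gene value and at least 20 reads over both libraries were tested (20223 introns). Fisher's exact test (two-sided) compared intronic and gene reads of the libraries, with Benjamini-Hochberg adjustment over all tested introns. An intron was called higher or lower at an adjusted p under 0.05 and at least 2-fold. The test compares these libraries, not the genotypes. Intervals are 95% intervals. For ratios they are exact (Clopper-Pearson) and cover counting error only, since amplified reads are not independent molecules. For retention ratios that is the error of intronic reads alone. Where said so, it includes that of gene reads, as the exact conditional interval of the odds ratio. For shares they are exact binomial intervals over introns. For medians they come from order statistics and reflect the spread among introns or genes. Both take these members as independent, although introns of the same gene share its gene reads. In simulated pairs of libraries with 18816 introns, intronic reads had counting (Poisson) error only and gene reads were held fixed. The calls recovered 12.8% of 2-fold, 66.7% of 4-fold, 97.9% of 8-fold and 100% of 16-fold changes, with 0 calls among unchanged introns. Without noise from amplification or between pools, this does not give the rate of false calls in the real libraries. Medians of lists were placed among 10000 random lists of the same size, each member drawn from the 100 features nearest in read depth (introns) or mean level (genes). These percentiles describe these libraries and are not p-values. Retention levels were given as the median coefficient and as the share of introns above the 90th percentile of other introns in wildtype.

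Gene levels were compared as log2 ratios of recovered reads over the authors' library sizes (pseudocount 0.5), for genes with at least 50 reads over both libraries. The plan had named the summed gene reads as the main scaling; since the deposited values already carried the authors' scaling it was kept, and the planned one was run as an alternative, which adds 0.02 to each log2 ratio. Of 23 gene lists fixed before the data were examined, 22 are described: the U12 list, minor and major spliceosome, nonsense-mediated decay, RNA export, ribosome biogenesis, unfolded protein response, heat shock, proliferation, exocrine and endocrine pancreas, liver, intestine, lens, photoreceptors, neurons, myelin and glia, muscle, cartilage and bone, skin, blood, and pigment cells.

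Named items followed a rule fixed beforehand, with 1 intron per gene. It took the 15 list introns with the largest rise and the 5 with the lowest ratio, the 5 other introns with the largest rise and the 5 with the largest fall, rnpc3, 3 members of each list with the largest absolute log2 ratio, and the 10 genes with the largest rise and the 10 with the largest fall among genes with at least 100 reads. Some items named by this rule are not reported here. Alternatives changed the read minimum, pseudocount, scaling, fold minimum, retention level and the introns entered. Scaling factors came from edgeR 4.0.16 (TMM) and DESeq2 1.42.0 (median ratio) in R 4.3.3, with no test from either tool. All other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.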

Results

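The series asks what happens to intron retention and gene expression in zebrafish larvae that are deficient in U12-type splicing. Introns and genes were read in 1 library of wildtype larvae and 1 library of clbn (caliban) mutant larvae, each from a pool of about 60 animals aged 108 hours. Both libraries were of similar depth, with 28309779 reads for wildtype and 25718058 for the mutant. Introns took 6.79% of reads in the wildtype library and 6.88% in the mutant library, and listed genes took 48.9% and 48.2%. The median intron held 7 reads in each library and the median gene 353 reads in wildtype and 332 in the mutant. There were no replicates, so no difference has a replicate check. Intervals of ratios cover counting error only, for retention ratios that of intronic reads unless gene reads are named. Those of medians and shares reflect the spread among introns or genes taken as independent.

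The gene mutated in clbn, as far as background knowledge goes, is rnpc3, which codes for a protein of the U11/U12 particle of the minor spliceosome. Its deposited gene value was 5.70 in wildtype and 2.503 in the mutant (273 and 109 reads), a ratio of 0.441 (0.349 to 0.551). Both of its tested introns were called higher relative to its own reads. The one at chromosome 24, 29862440 to 29867911, went from 9 to 32 reads, an 8.54-fold rise relative to the gene (3.97 to 21.8 with gene reads counted in the error, adjusted p = 9.8e-08 by Fisher's exact test), with a log2 ratio of 1.91 when scaled by the library total. The other, at 29886000 to 29889396, had 66 and 60 reads, which was 2.27-fold higher relative to the gene (1.47 to 3.52 likewise, adjusted p = 0.0048). Scaled by the library total this second intron had a log2 ratio of 0.0021 and no call, so that its call rests on the lower gene reads.

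Introns of genes on the U12 list rose in the mutant library and none was called lower. Of 155 tested introns in 50 of these genes, 38 introns in 30 genes rose (24.5%, 18.0 to 32.1%). Among 20068 other introns, 552 rose (2.75%, 2.53 to 2.99%) and 296 fell (1.47%, 1.31 to 1.65%). Random lists matched on depth held 5.08 higher introns on average and 14 at most, so the list lay above 100% of them. With the adjustment over the list alone, 40 introns rose and 0 fell. At an unadjusted p under 0.05 and at least 2-fold the list had 43 higher and 3 lower introns. A list with no lower call was not rare by itself, since 10.9% of random lists had none. Of the list introns, 23 rose at least 4-fold and 14 at least 8-fold, against 0 lower at either size.

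Among calcium channel subunits, cacna1ba had 1 and 40 reads in the intron at chromosome 5, 31119359 to 31123265, a ratio of 34.4 with a counting interval of 8.63 to 2062. An intron of cacna1c also had 1 and 40 reads (ratio 30.2, chromosome 4, 19308289 to 19311753). For the gene itself 9 and 8 reads were recovered, and with their error counted in the odds ratio was 40.9 (4.67 to 2019). As the smallest whole solution, these gene reads may be too low by a common factor, which would make this interval too wide. One of cacna1da went from 13 to 81 (8.10-fold, 4.62 to 16.4, chromosome 11, 37756376 to 37796602). An intron of the sodium channel gene scn8aa had 3 and 33 reads (ratio 10.1, 3.66 to 59.4, chromosome 23, 27555748 to 27558732). Ratios on few wildtype reads depend on the pseudocount, and with 5 in place of 0.5 the log2 ratio of cacna1ba went from 5.10 to 3.26 and that of cacna1c from 4.92 to 3.07.

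An intron of the MAP kinase gene mapk14a (p38) at chromosome 8, 24703018 to 24708627, went from 18 to 208 reads, a 9.30-fold rise (5.88 to 16.4, adjusted p = 2.1e-28, Fisher's exact test). Genes of protein export and degradation at the endoplasmic reticulum were derl1 (1 and 20 reads, ratio 11.2, 2.63 to 681, log2 ratio 1.77 with pseudocount 5, chromosome 16, 27887136 to 27888766), derl3 (4 and 24 reads, 8.79-fold, 3.33 to 38.4, chromosome 8, 31771924 to 31773683) and the signal peptidase subunit spcs2 (3 and 28 reads, ratio 7.91, 2.80 to 46.6, chromosome 15, 4854029 to 4856177). Nuclear proteins were represented by the RNA polymerase II subunit gene polr2eb (2 and 51 reads, ratio 19.3, 6.30 to 203, chromosome 22, 17832122 to 17833275), parp1 (4 and 48 reads, 10.4-fold, 4.26 to 44.4, chromosome 20, 43718765 to 43720720) and ctnnbl1 (3 and 26 reads, ratio 8.57, 3.01 to 50.6, chromosome 2, 54312388 to 54314886). A further list intron that rose lies in atxn10 (2 and 18 reads, ratio 7.87, or an odds ratio of 9.36, 1.98 to 89.8, with the error of its 33 and 31 gene reads, chromosome 4, 17789244 to 17794244). The 5 list introns with the lowest ratio were in stk11, derl1, plcg1, gtf2h1 and ctnnbl1, at log2 ratios of -1.49 to -1.25, and none of them was called.

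**Figure D1:**
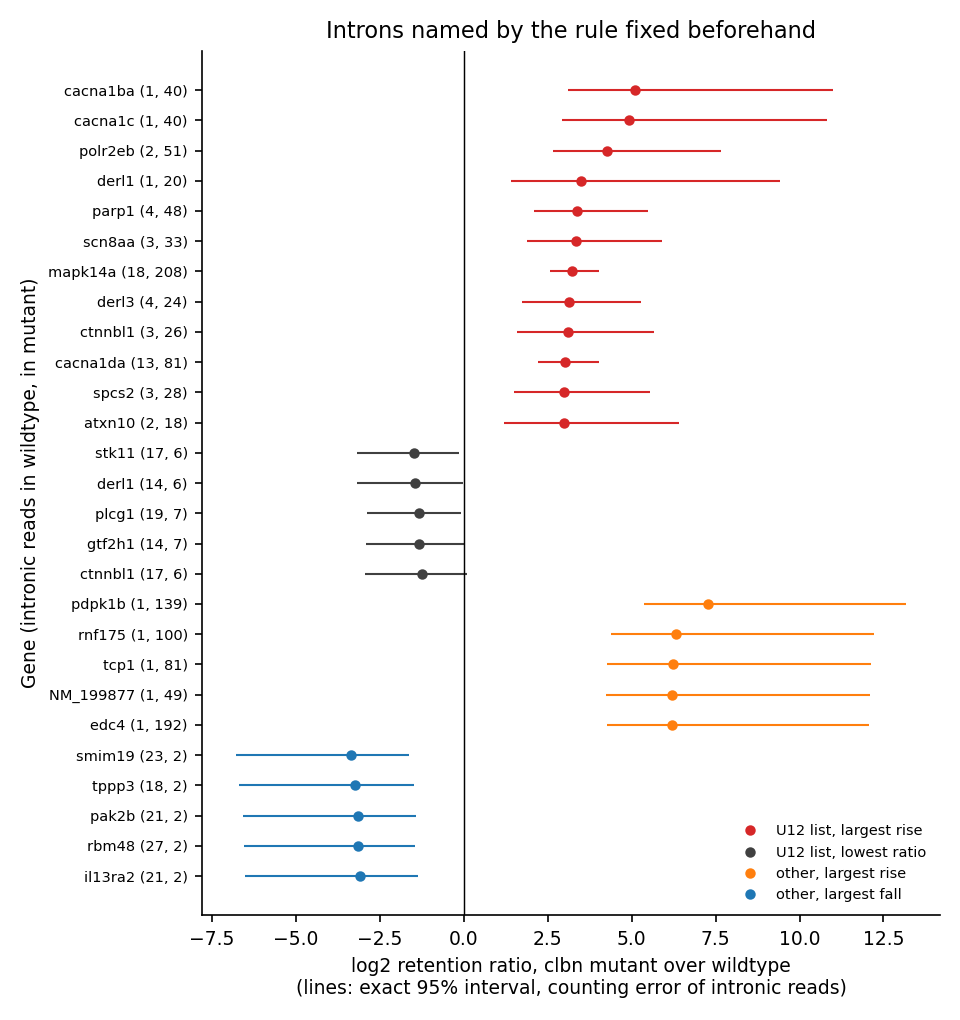
Retention ratio of the introns named by the rule fixed beforehand, as log2 of mutant over wildtype (horizontal axis), with exact 95% intervals for counting error of intronic reads and the intronic reads of both libraries beside each gene. The 12 list introns shown with the largest rise lie between 2.98 and 5.10, and their intervals exclude 0.

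The median log2 ratio over list introns was 0.21 (0.11 to 0.52) against 0.03 for other introns, a difference of 0.18. This median lay above 99.75% of matched random intron lists. With only the intron with most reads in each gene, the difference was 1.204, but that choice favours retained introns in both classes. It was 0.49 with a minimum of 50 reads and 0.12 with a minimum of 5 reads. On plus strand genes alone (52 list introns) it was 0.40, and on minus strand genes (103 list introns) 0.16. The quartiles of the list were -0.21 and 1.34, and those of other introns -0.38 and 0.43.

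Most genes with a higher intron, those of the U12 list included, had a single one. Some of these list genes, such as atxn10, had only 1 tested intron, so they could hold no more. Several higher introns were found in list genes such as cacna1ba (3 of 8 tested), dctn3 (2 of 2) and mapk14a (2 of 2). Higher introns were found in 517 genes in all, 447 of them with exactly 1, and of the 431 with at least 2 tested introns 361 had exactly 1. Calls were more numerous in the higher direction, with 590 higher and 296 lower introns over all genes, 311 and 95 at 4-fold and 128 and 7 at 8-fold. With intronic reads scaled by the library total, 745 other introns rose and 500 fell. The other introns with the largest rise were in pdpk1b, a kinase of the insulin pathway (1 and 139 reads, ratio 156, 41.1 to 9267, log2 ratio 7.28, or 5.33 with pseudocount 5, chromosome 24, 38832437 to 38832842), rnf175 (1 and 100 reads, ratio 79.6, 20.8 to 4740, chromosome 1, 9114125 to 9115891), tcp1, a chaperonin subunit (1 and 81 reads, ratio 74.6, 19.4 to 4447, chromosome 23, 2444619 to 2446297), a gene listed without a symbol (1 and 49 reads) and edc4, a decapping factor (1 and 192 reads, ratio 73.0, 19.4 to 4335, chromosome 18, 21668996 to 21671092). The largest falls were in smim19 (23 and 2 reads, ratio 0.0969, 0.0091 to 0.321, chromosome 14, 22240510 to 22242879), tppp3, pak2b, rbm48 and il13ra2, all with 2 reads in the mutant library and called lower.

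**Figure D2:**
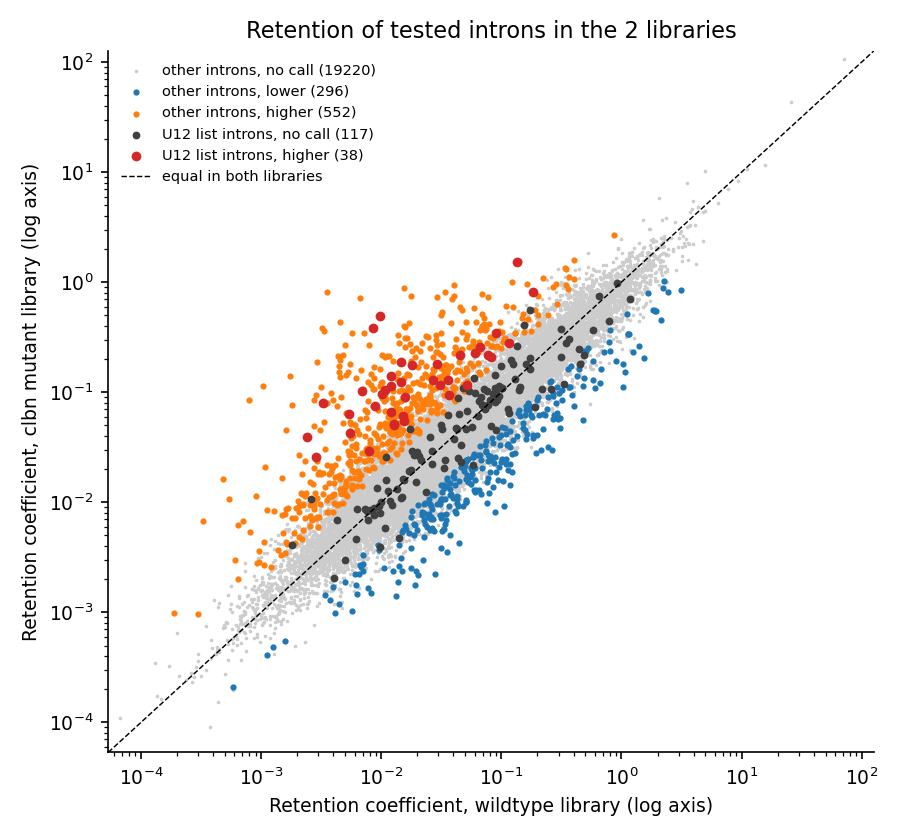
Retention coefficient (intron level over gene level) of the 20223 tested introns in the wildtype library (horizontal, log axis) and the mutant library (vertical, log axis), one point per intron. Of the 155 introns in U12 list genes, 38 were called higher and none was called lower. By the rule for a call, the 38 must lie above the line of equality.

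In level, list introns had a median retention coefficient of 0.0420 (0.0264 to 0.0571) in wildtype and 0.0760 (0.0544 to 0.0964) in the mutant library. With a minimum of 5 reads these medians were 0.0351 and 0.0461. Other introns had 0.0322 and 0.0329. The share of list introns above a coefficient of 0.319, the 90th percentile of other introns in wildtype, was 7.10% (3.60 to 12.3%) in wildtype and 8.39% (4.54 to 13.9%) in the mutant library. These are 11 and 13 of the same 155 introns, so the intervals do not measure the difference between the shares. For other introns the share was 10.0% and 10.2%. Above 0.5 times that level, the share of list introns was 13.5% in wildtype and 22.6% in the mutant library.

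Transcripts of U12 list genes did not stand apart in level. Their median log2 ratio over 59 genes was 0.08 (-0.01 to 0.13) against 0.05 for 9865 other genes, at percentile 73.5 of matched random lists. The kinase gene mapk8a was 2.16-fold higher (1.80 to 2.60), derl2 had a ratio of 1.79 (1.48 to 2.16) and cacna1sa one of 0.531 (0.431 to 0.649). No list gene was at least 2-fold lower. The 29 list genes with a higher intron had a median log2 gene ratio of 0.11, from -0.55 to 1.11.

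Digestive enzymes of the exocrine pancreas were the gene group that differed most. Of 16 measured members, 15 were at least 2-fold lower in the mutant library, and the list median was -1.62 on the log2 scale (-1.81 to -1.49), below 100% of random lists. Amylase (amy2a) was 4.67-fold lower (4.49 to 4.85), with 16041 reads in wildtype and 3123 in the mutant. The bile salt-dependent lipases cel.1 and cel.2 were 3.97-fold (3.81 to 4.15) and 3.90-fold lower (3.57 to 4.27). Trypsin (prss1) had a ratio of 0.326 (0.321 to 0.332), and the trypsinogen, chymotrypsin, elastase and carboxypeptidase genes of the list ranged from 0.285 to 0.372. Enzyme families with close copies can share reads, so ratios of single members are less certain. The transcription factor gene ptf1a, which acinar precursors and some neurons use, was the exception at 1.15 (0.842 to 1.59). The endocrine list, many of whose members neurons also use, had a median of 0.05 (-0.13 to 0.31) over 10 genes (-0.0016 with median ratio scaling), with gcga (glucagon) at 1.72 (1.34 to 2.23), pax6b at 1.24 and nkx2.2a at 1.17. Of its members 4 were below 0 on the log2 scale, among them the hormone genes ins (0.916, 0.7999 to 1.05) and sst2 (0.891, 0.768 to 1.03), named after their values were seen.

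Lens genes were lower throughout. All 17 measured members were below 1 and 6 were at least 2-fold lower, with a median of -0.87 (-1.08 to -0.67), below 100% of random lists. The crystallin genes crybb1, crygn1 and cryba1a had ratios of 0.413 (0.402 to 0.423), 0.418 (0.285 to 0.594) and 0.439 (0.308 to 0.611). Photoreceptor genes moved less, with a median of -0.08 (-0.18 to 0.09) over 27 genes at percentile 0.52. Within them the cone genes gnat2 and pde6c had ratios of 0.751 (0.728 to 0.775) and 1.36 (1.29 to 1.44), and opn1mw2 had 1.39 (0.909 to 2.13).

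For the intestine the median was -0.18 (-0.47 to -0.10) over 17 genes, 15 of them below 0, at percentile 0.09. The peptide transporter slc15a1b had a ratio of 0.556 (0.517 to 0.598) and ada one of 0.570. For the liver the median was -0.14 (-0.48 to 0.04) over 27 genes at percentile 0.01, with 19 genes below 0 and 8 above. The cytochrome P450 gene cyp3a65 and the fetuin gene ahsg1 were the 2 members at least 2-fold lower, with ratios of 0.268 (0.260 to 0.277) and 0.291 (0.220 to 0.376), and cyp2ad2 had 0.546. The main liver fatty acid binding protein, fabp10a, had a ratio of 1.04 (0.999 to 1.09), and the apolipoprotein gene apoa1a one of 1.16 (1.14 to 1.18), both named after their values were seen.

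Major spliceosome genes had a median of 0.32 (0.23 to 0.45), with 24 of 25 members above 0, above 100% of random lists. The Sm and U2 protein genes snrpa1, snrpd1 and snrpd2 had ratios of 1.74, 1.59 and 1.56. Ribosome biogenesis had a median of 0.33 (0.12 to 0.49) over 21 genes at percentile 100, led by gar1 (1.67), fbl (1.59) and dkc1 (1.58). Proliferation genes had 0.37 (0.18 to 0.52) over 16 genes at percentile 99.99, led by tyms (1.53), ccnb2 (1.48) and pcna (1.45). Not one gene of these lists was 2-fold higher. The median of all 9924 genes was 0.05, and TMM or median ratio scaling changes it and each list median alike by -0.05.

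Stress lists held a few higher members. Heat shock genes had 0.29 (-0.0039 to 0.73) over 11 genes at percentile 99.87, with the mitochondrial chaperonins hspd1 and hspe1 at 1.72 (1.62 to 1.83) and 1.39 (1.24 to 1.57) and hspa4a at 1.66. The unfolded protein response list had 0.16 (0.02 to 0.35) over 20 genes at percentile 97.44, with the chaperones hspa5, hyou1 and calr3b at 1.59, 1.498 and 1.48. Its median was 0.0747 without hsp90b1, the 1 member with a recovered length under 200 bp (136 bp). That length is the smallest whole solution and may be too low by a common factor, so hsp90b1 need not be short.

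Among the remaining lists, the minor spliceosome had a median of 0.19 (-0.41 to 0.39) over 11 genes at percentile 87.85, with rnpc3 the lowest, scnm1 at 1.44 (0.866 to 2.42) and zcrb1 at 0.753 (0.586 to 0.962). Nonsense-mediated decay had 0.09 over 10 genes (rbm8a 1.33, magoh 1.31, eif4a3 1.15) at percentile 71.23, and RNA export 0.10 over 10 genes (alyref 1.32, ddx39ab 1.305, thoc7 0.778) at percentile 80.08. Muscle had 0.10 over 32 genes (desmb 0.579, pvalb3 1.61, tnni2b.1 0.730) at percentile 98.4, and cartilage and bone 0.14 over 13 genes (col2a1a 1.28, col9a2 1.25, col9a1a 1.199) at percentile 97.12. Neuronal genes had -0.01 over 22 genes, or 0.01 with scaling by summed gene reads (neflb 1.18, vamp1a 0.852, snap25a 0.853) at percentile 22.07. Myelin and glia had 0.09 over 11 genes at percentile 78.02, although the myelin genes mpz and plp1b had ratios of 0.519 (0.396 to 0.672) and 0.533 (0.460 to 0.615) and the glial gene fabp7a 1.32. Skin had 0.06 over 18 genes (agr1 1.37, icn 1.32, anxa1a 0.842) at percentile 80.55 and pigment cells -0.08 over 11 genes (slc45a2 0.678, pnp4a 1.35, mlpha 0.813) at percentile 7.86. Blood had -0.24 over 7 genes at percentile 1.02, with ikzf1 at 0.510 (0.327 to 0.769), lyz at 0.706 and the embryonic globin hbae3 at 1.37.

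**Figure D3:**
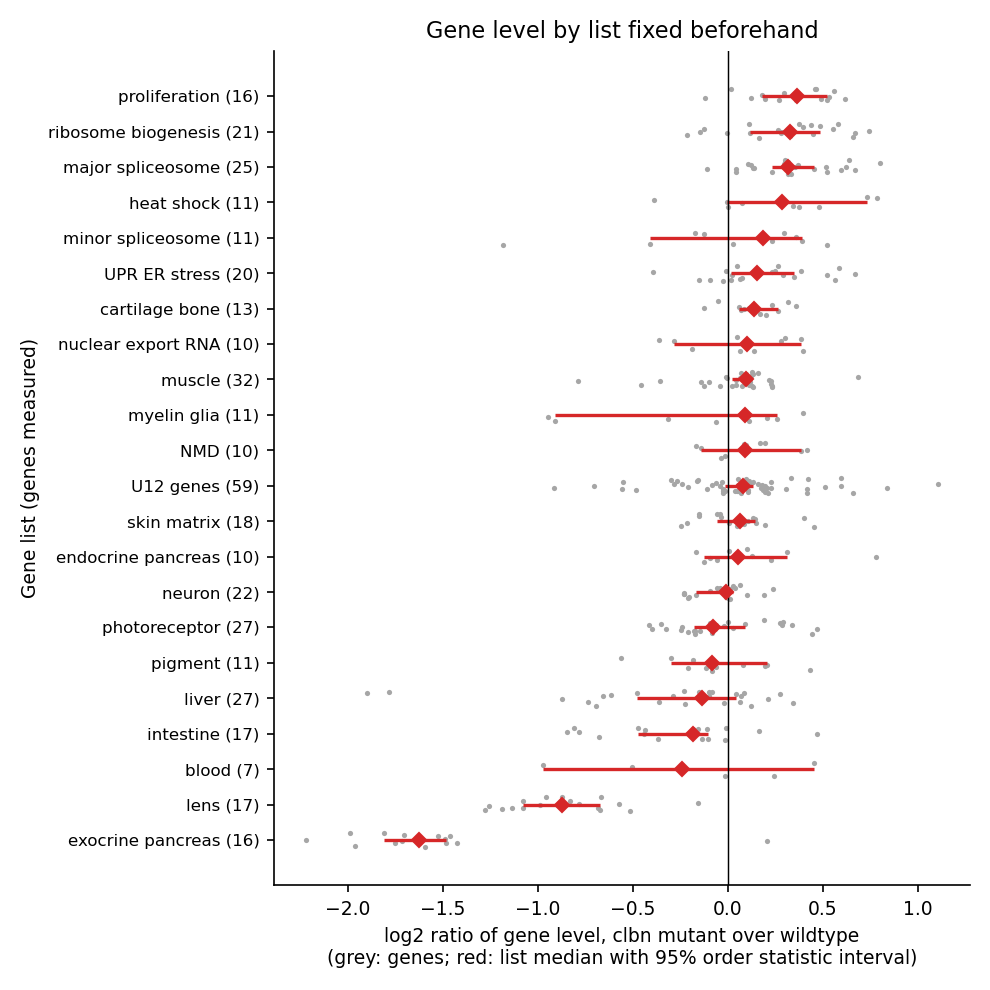
Log2 ratio of gene level, mutant over wildtype (horizontal axis), for 22 gene lists fixed beforehand (vertical axis, number of measured genes in brackets), with grey points for genes and a red diamond and line for the list median and its 95% interval. The exocrine pancreas and lens lists stand at medians of -1.62 and -0.87, and the other lists lie between -0.24 and 0.37.

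Over all 9924 genes, 68 were at least 2-fold higher and 94 at least 2-fold lower in the mutant library. Among the 10 genes with the largest rise were enzymes of cholesterol synthesis, with squalene epoxidase (sqlea, 3.89-fold, 3.29 to 4.63), mevalonate kinase (mvk, 3.68-fold, 2.62 to 5.35) and lanosterol synthase (lss, 2.65-fold, 1.78 to 4.08). Others were zgc:113229 (3.16-fold), the chemokine gene ccl34b.1 (3.14-fold), a gene without a symbol (2.80-fold), the mitochondrial phosphatase gene ptpmt1 (2.78-fold), pibf1 (2.69-fold) and the ciliary transport gene ift88 (2.61-fold). The 10 genes with the largest fall were the lens gene grifin (4.87-fold lower, 3.58 to 6.89), amy2a, selenoe (4.43-fold lower), the elastase gene cela1.3 (4.12-fold lower), cel.1, cel.2, cyp3a65 (3.73-fold lower), the astacin protease gene c6ast4 (3.65-fold lower), the lens membrane gene lim2.5 (3.53-fold lower) and the carboxypeptidase gene cpb1 (3.51-fold lower).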

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

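Introns without a gene value were outside every comparison above, and all tests here were chosen after the data had been seen, the division of reads by the number of Refseq IDs after a first count of calls. Of 596 such introns with at least 20 reads over both libraries so divided, 17 were higher in the mutant library and 21 lower when scaled by the library total (Fisher's exact test, adjusted p under 0.05, at least 2-fold). What drew attention was signal above the wildtype level in the 17 introns, but calls in this set did not lean to the higher side. An 8-fold rise was reached by 3 introns, and 0 introns were lower by as much. The pair of them in ccnt2a, a cyclin gene of transcription elongation, are at chromosome 9, 24274814 to 24275159 (3 and 41 reads, ratio 13.1, 4.80 to 75.9) and 24275242 to 24275817 (7 and 56 reads, 8.29-fold, 4.004 to 22.9). An intron of irge4 had 3 and 26 reads (ratio 8.33, 2.92 to 49.2). An intron of e2f5, a transcription factor gene that is on the U12 list but had no gene value, had 3 and 18 reads (ratio 5.82, 1.93 to 35.0, adjusted p = 0.0096).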

How the results depend on the processing

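Strand subsets, the exact binomial test and the minimum of 50 gene reads were chosen after seeing the data. So was the removal of genes with a recovered length under 200 bp. All other alternatives were chosen before the data were examined, except scaling by summed gene reads. Planned as the main scaling, it was made an alternative after seeing the data. No paired analysis was possible because each genotype has 1 library. Class from splice site sequence was not run, since no genome of the build was at hand, and of overlaps with other genes only those with another listed intron could be left out (1387 introns of the table). Of the values of main results under alternatives, 180 stayed within their interval or within 1.5 times the count and 32 moved further. None changed sign beyond its interval, but the endocrine median (0.05) became -0.0016 with median ratio scaling and the neuronal median (-0.01) became 0.01 with summed gene reads. The difference of medians of 0.18 moved to 1.204 with the 1 intron of most reads per gene, a choice that favours retained introns, and within its interval to 0.49 with 50 reads and 0.40 on the plus strand; its other values were 0.12 to 0.21. The unfolded protein response median of 0.16 became 0.0747 without hsp90b1, its 1 member with a recovered length under 200 bp. A missed common factor could also give that length. Counts are given in the order list higher, other higher, other lower (main 38, 552 and 296), with 0 list introns lower in each setting. They were 23, 288 and 95 at 4-fold, 22, 284 and 133 with 50 reads, 15, 233 and 108 on the plus strand and 23, 318 and 185 on the minus strand, each with fewer introns able to pass. Without a fold minimum 450 other introns fell, and 500 with the library total, where the cause was not tested. Median coefficients moved with a minimum of 5 reads to 0.0461 for list introns in the mutant library and to 0.0278 and 0.0285 for other introns in wildtype and mutant, and with 50 reads to 0.0363 and 0.0382 for other introns; the cause was not tested. Shares of other introns above the level were 7.92% and 7.81% with 5 reads and 12.2% and 12.9% with 50 reads. At 0.5 times the level, shares were 13.5% and 22.6% for the list and 18.4% and 18.8% for other introns, and at the doubled level 2.58% and 3.23%, and 4.34% and 4.14%, as another level must give. Among 128 values of 32 named introns, 1 lost its call, the second rnpc3 intron with the library total (log2 ratio 0.0021), and with pseudocount 5 the sizes of 20 moved by over 1.5 times, all toward no change. Among 340 values of 85 named genes, 13 moved beyond their counting interval with no change of direction. In the simulation 2-fold changes of introns were mostly missed (12.8% called), which reflects the 2-fold minimum for a call as well as the depth.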

Other observations

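The intron groups, the pairs and the tests on them were chosen after values had been seen, as were the tests on scaling, noise, unspliced RNA, gene values, the U12 list count, islet hormone genes and ptf1a, whereas only the tests of retained introns in exocrine genes and of unseen sterol genes were written first.

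Outside the U12 list, 114 introns were at least 8-fold higher in the mutant library and 7 at least 8-fold lower. Genes of 2 kinds were picked out after their values were seen, and no enrichment was tested. Palmitoyltransferase genes among the higher ones were zdhhc5a (1 and 68 reads), zdhhc17 (4 and 192), zdhhc13 (2 and 43), zdhhc14 (1 and 23) and zdhhc8b (3 and 49), together with golga7 (5 and 44 reads) and golga7ba (4 and 67), whose products belong to such an enzyme complex in mammals. Genes of protein entry into the secretory pathway were spcs3 (2 and 73 reads) and srp68 (1 and 26). The intron with the most mutant reads in this set was in ssu72, a phosphatase gene of RNA polymerase II, at chromosome 22, 381397 to 387231, with 74 and 924 reads (15.1-fold, 12.0 to 19.5). In prox1a, a transcription factor gene of liver, pancreas and lens, an intron at chromosome 17, 33063744 to 33067218, had 17 and 356 reads (15.6-fold, 9.89 to 27.9), while the gene level differed by 0.52 on the log2 scale.

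Most genes of sterol synthesis were higher. Of 27 listed genes of sterol synthesis, uptake and transport 22 were measured, 20 were above 0 and 7 at least 2-fold higher, with a median log2 ratio of 0.59 (0.32 to 1.32). Beyond the top genes, pmvk had a ratio of 2.499 (1.63 to 3.98), mvda 2.09 (1.51 to 2.96), nsdhl 1.84 (1.55 to 2.19), idi1 1.74 (1.598 to 1.90) and hmgcs1 1.66 (1.55 to 1.77), whereas the uptake receptor gene ldlra had 0.883 (0.815 to 0.957) and the sterol transport gene stard4 0.804 (0.662 to 0.973). Of fatty acid synthesis genes 6 were measured, with a median of 0.16 (-0.45 to 1.07) at percentile 91.21.

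More introns were higher than lower in the mutant library. All 2470 tested introns of the 517 genes with a higher intron, the called ones included, had a median log2 ratio of 0.278 (0.225 to 0.328). This argues against more unspliced RNA or genomic DNA that raised the introns of these genes evenly by at least 1 on that scale. Over the 20068 introns outside the U12 list, called ones included, the median log2 ratio was 0.03. Listed introns took 6.79% of reads in the wildtype library and 6.88% in the mutant library. These values argue against a rise over introns in general between these libraries. A smaller or uneven rise from either source in part of the introns stays open, since medians and totals cannot exclude it. Lower gene values are not the main source, since 94.6% of higher introns also had at least 2-fold more reads by library total. Read noise beyond counting error stays open for single introns, since the 296 lower calls have no tested source, and the ratio of higher to lower calls (1.99, or 3.27 at 4-fold and 1.57 with the library total) is the pattern itself. Deficient U12-type splicing is a candidate explanation for the introns of the U12 list, whose count lay above 100% of matched random lists, and for the 552 other introns it stays open without their splice sites.

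Exocrine pancreas genes were lower in the mutant library. Library scaling cannot account for it, as the list median was at most -1.601 under the other 3 scalings. Retained introns in the enzyme genes themselves are argued against by 1 of 14 genes with a tested intron (7.14%) that held a higher one, cpa1. A smaller share of pancreas of every kind is argued against by the islet hormone genes ins, gcga and sst2, whose ratios had lower limits of 0.768 or more, against an exocrine median ratio of 0.325, unless hormone RNA per cell rose or, for gcga, gut cells supplied it. Fewer acinar cells and less enzyme RNA per cell cannot be told apart, because ptf1a (ratio 1.15, 0.842 to 1.59) is also used outside the pancreas.

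For the sterol genes, the 17 measured members whose values had not been seen had a median of 0.49 (0.31 to 0.73), above 100% of matched random lists, so the rise was not confined to the genes that prompted the test. Scaling moves all genes alike, and these members lay 0.43 above the median of all genes. A raised sterol synthesis programme may be linked to insig1, which codes for a protein that holds the sterol sensor back: 1 of its 4 tested introns, at chromosome 7, 43742165 to 43742963, went from 7 to 342 reads (39.7-fold, 20.4 to 106, adjusted p = 2.3e-68, Fisher's exact test). No test here bears on that link, and an intron of mbtps2, whose product activates the same pathway, was also higher (21 and 138 reads, 7.21-fold, 4.63 to 12.3). In gene level insig1 was itself higher in the mutant library, at a ratio of 1.27 (1.15 to 1.39), and mbtps2 had 0.984 (0.865 to 1.12). Loss of digestive function is an untested alternative.

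Both genes of some pairs held a higher intron, more often than chance pairing gave. Among 509 pairs of genes named with a and b and both tested, 18 had a higher intron in both, against 3.99 on average and 15 at most when calls were shuffled among genes of similar intronic depth. Of these pairs 15 had no gene on the U12 list, among them kifap3a and kifap3b, tspan13a and tspan13b, pdpk1a and pdpk1b, and cul1a and cul1b. Whether the introns of a pair lie at the same place, and whether such copies share reads, was not tested.

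A retained intron could go with a lower level of its own gene, but these data do not decide it. The sets of genes were redefined after a first version had been seen, which took all calls by library total and gave a median above 100% of random lists. Genes with an intron at least 8-fold higher by library total (128 genes) had a median log2 ratio of 0.12 at percentile 99.64, and genes with an intron 8-fold higher relative to gene reads (117 genes) had -0.05 at percentile 0, since each way of calling favours 1 direction.

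The table lists 20758 introns of plus strand genes and 34902 of minus strand genes, or 3.95 and 6.08 introns per Refseq ID.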
